A study of Drosophila melanogaster with 26 samples.

How the data were processed

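Small RNAs were profiled in 26 libraries from Drosophila melanogaster, each the single library of its group. Per the labels, 25 came from ovaries of flies aged 4 to 6 days and kept at 25 °C, and the other was from ovarian somatic cells (OSC), a cell line of somatic follicle cell origin. Of these, 12 libraries share a table of sequences and 14 are reporter libraries with a table of positions each. Group membership came from the labels, and each column of the shared table was matched to a sample by its name; 0 columns were left over. The column taken as the Aub IP of the zucchini knockdown carries a name that differs from the other Aub columns by 1 added digit. The column taken as the germline GFP-Piwi IP was likewise matched by its name alone.

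The shared table holds raw read counts per distinct sequence, deposited by the authors without scaling. The submitters' processing notes name cutadapt 1.0, Bowtie 0.12.7 and the dm3 build, with no role or order given; mismatch and multi-mapping settings are not given in the sources used here. The labels describe reads of 18 to 29 nt, whereas the table runs from 23 to 30 nt and holds 19959489 distinct sequences, so a column total is not the depth of the library and 21 nt RNAs were out of reach. Totals per column lay between 5520656 and 30691075 reads.

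The reporter tables give a signal per position and strand, deposited after division by 1 factor per library; per the file headers the columns are a position and the plus and minus strand, and the denominator is not given in the sources used here. All values up to 20 reads were whole multiples of 1 step per library within a tolerance of 0.02 reads (100% in each library), so reads were recovered by division. That positions are 5′ ends was inferred from the 10 nt offset of the strands. Without the reporter sequences, the target sites were taken from the antisense positions with the most reads. The control target has no such peak at its site, so its zones use the site position of the matched trigger reporter, although its map is 1747 nt long against 1751 nt.

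Genome coordinates were not used here. Overlapping sequences were joined into contigs by greedy extension over 20 nt words present in at least 2 distinct sequences, after removal of reads that match 2S rRNA, 3 tRNAs or 26 microRNAs. This gave 14035 contigs of at least 100 nt (median 140 nt, longest 20808 nt, total 3078529 nt). Reads were placed by exact match, and 54.2% to 78.5% of the reads of 23 to 29 nt had a place. Contigs stand where genome windows were planned, and they bear no coordinates, gene models or multi-mapping information. A contig can join related copies of an element.

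Numbered retrotransposons are written with the prefix DM (DM297, DM412, DM1731), which the plots leave out. Elements were named by exact or 1-mismatch matches of published RT-PCR primers, listed from general knowledge. Of 50 primer pairs tried, 23 elements were found, 17 by a pair at most 400 nt apart and 6 by a single exact primer of at least 20 nt near a contig end; the window ran 500 nt to either side. A window therefore stands for part of an element, and sense means the strand of the forward primer. Of 10 lists fixed before the data were examined, 4 had no member with a value: the somatic genic sources (8 genes listed), the endo-siRNA hairpins (2), the piRNA pathway genes (18) and the suppressor-like repeat loci (3). Values were had for 1 of 3 dual-strand clusters, 2 of 2 uni-strand clusters, 3 of 6 soma-dominant, 6 of 10 germline-dominant and 11 of 20 other transposons, and for 15 of 15 microRNAs, which served for scaling only.

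From reads of 23 to 29 nt, the ping-pong share is the percentage of 5′ to 5′ overlaps of 1 to 25 nt on opposite strands that are 10 nt, weighted by the product of read counts. The phasing share is the percentage of distances of 1 to 50 nt from a 3′ end to the next 5′ end on the same strand that are 1 nt. An even spread gives 4% and 2%. Only ends with their whole distance window on the contig counted. The +1 U share is the percentage of reads followed by U, with the U share at +2 to +10 nt as background. Element and contig levels are in rpm, counted over the reads of 23 to 29 nt, and ratios are log2 ratios of 2 libraries; a count of 0 was replaced by 3 counts. The named items were those fixed in advance: list members with at least 100 reads over both libraries, the 8 contigs highest and the 8 lowest among those with at least 1000 reads and a 2-fold ratio, and the 5 highest reporter positions downstream of the target. Contigs were called higher or lower at a ratio of at least 2-fold, with no test. A list median is given with its percentile among 10000 random lists of contigs of the same size and like abundance. Contigs were classed as OSC-enriched or Aub-enriched where OSC and the control Aub IP differed 8-fold (1 rpm added).

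With 1 library per group there is no replicate check: no p-values were computed, and every ratio compares 2 libraries, not the conditions behind them. Intervals are 95%. Ping-pong, phasing and +1 U shares and their changes have intervals from 500 resamples of contigs, which reflect the spread between contigs. The other intervals cover counting error only: exact binomial (Clopper-Pearson) for shares and exact Poisson for ratios and reporter signals. The scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0, pandas 2.3.3 and matplotlib 3.10.9. In 6 simulated data sets the ping-pong and phasing shares came within 8.42% of their true values. These data sets held 40 unrelated random sequences each, with true ping-pong shares of at most 10.2%. They therefore do not check contigs that join related copies, or shares as high as those of Aub and AGO3. In simulated ratios, run for each knockdown comparison, 200 contigs changed 4-fold were all recovered (100%) and 0% of the unchanged contigs were called. These ratios held Poisson counting error only, around a mean shared by both libraries. They check the computation and cannot give the rate of false calls between real libraries, which also differ in IP and preparation. IP ratios are relative to the rest of the same library, so each was also scaled to microRNA reads (here only those of 23 nt or more), to reads without 2S rRNA, tRNA and microRNA, and to the median contig; a direction is stated as holding only if all 4 scalings gave it.

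Chosen after the data were examined were the contigs and their length and edge rules, the list of known RNAs, the primers (some added after the earlier matches), the rule for single primers, the class threshold, and the start of the U-run grid, which was set at the highest position of the same data. Alternatives to pair weights, read length, word minimum, read minimum, scaling, window and strand are given at the end. The levels of rhino and zucchini transcripts cannot be read from small RNAs of 23 to 30 nt, so the knockdowns carry no check here.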

Results

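The 12 libraries of the shared table held PIWI protein immunoprecipitations (IPs) and total small RNA. Control, rhino and zucchini germline knockdown ovaries each gave a Piwi, an Aub and an AGO3 IP. Control ovaries also gave an IP of GFP-tagged Piwi expressed in the germline, the zucchini knockdown a total small RNA library, and OSC a total small RNA library. Each group was 1 library. Reads of 23 to 29 nt numbered 4955412 in the AGO3 IP of the zucchini knockdown, the lowest, and 29610676 in the control Aub IP, the highest. In 14 further libraries, small RNA ends were mapped along reporter transgenes, with 25 to 4123 sense reads per reporter.

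The control IPs set the small RNAs of the 3 PIWI proteins beside each other. Piwi is nuclear and acts in germline and follicle cells, while Aub and AGO3 are the cytoplasmic partners of the ping-pong cycle in the germline. The 6 measured germline-dominant transposons had a larger sense share in AGO3 than in Aub. Sense reads made up 94.97% of I-element reads in AGO3 against 31.5% in Aub, 90.9% against 15.9% for jockey, 90.5% against 14.7% for Max-element, 85.4% against 14.04% for Burdock and 84.85% against 14.3% for TART. HeT-A was mostly sense in both, at 96.8% and 57.65%, and in Piwi, at 84.2%. AGO3 held the larger sense share in 17 of 23 elements, the exceptions being DM1731, ZAM, copia, gypsy, invader1 and roo. The 3 measured soma-dominant transposons and flamenco had higher levels in Piwi than in Aub or AGO3. flamenco, a uni-strand cluster of follicle cells, gave 592 rpm in Piwi, 9.69 in Aub and 25.9 in AGO3, and the retrotransposon gtwin gave 630.2, 50.4 and 63.5. ZAM gave 105.9, 4.05 and 7.71, and gypsy, with the smallest contrast, 1557, 657 and 548.

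The ping-pong share was 57.2% in Aub (95% interval over contigs 51.2 to 66.4) and 63.8% in AGO3 (49.5 to 76.4), against 5.25% in Piwi (4.84 to 5.96) and 4% for an even spread. In Piwi the most frequent overlap was not 10 nt but 19 nt, at 5.68%. Between Aub and AGO3 reads the ping-pong share was 70.4% (62.6 to 77.6). Phasing went the other way. The phasing share was 5.05% in Piwi (4.81 to 5.25), 2.91% in Aub (1.94 to 3.58) and 1.23% in AGO3 (0.897 to 1.73), with 2% for an even spread, and 1 nt was the most frequent distance in Piwi alone of the 3. U followed 57.7% of Piwi reads, 49.4% of Aub reads and 37.5% of AGO3 reads, with backgrounds of 31.1%, 31.3% and 26.1%. Reads began with U in 79.1%, 78.8% and 45.4% and had A at base 10 in 28.1%, 37.97% and 73.8%, and the modal lengths were 26, 25 and 24 nt. With each sequence counted once, U began 64.4%, 56.4% and 46.0%, and A was at base 10 in 29.8%, 32.9% and 44.7%. With each position counted once in place of its reads, the ping-pong shares lay near the even share, at 4.18% in Aub, 4.69% in AGO3 and 4.03% in Piwi.

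**Figure D1:**
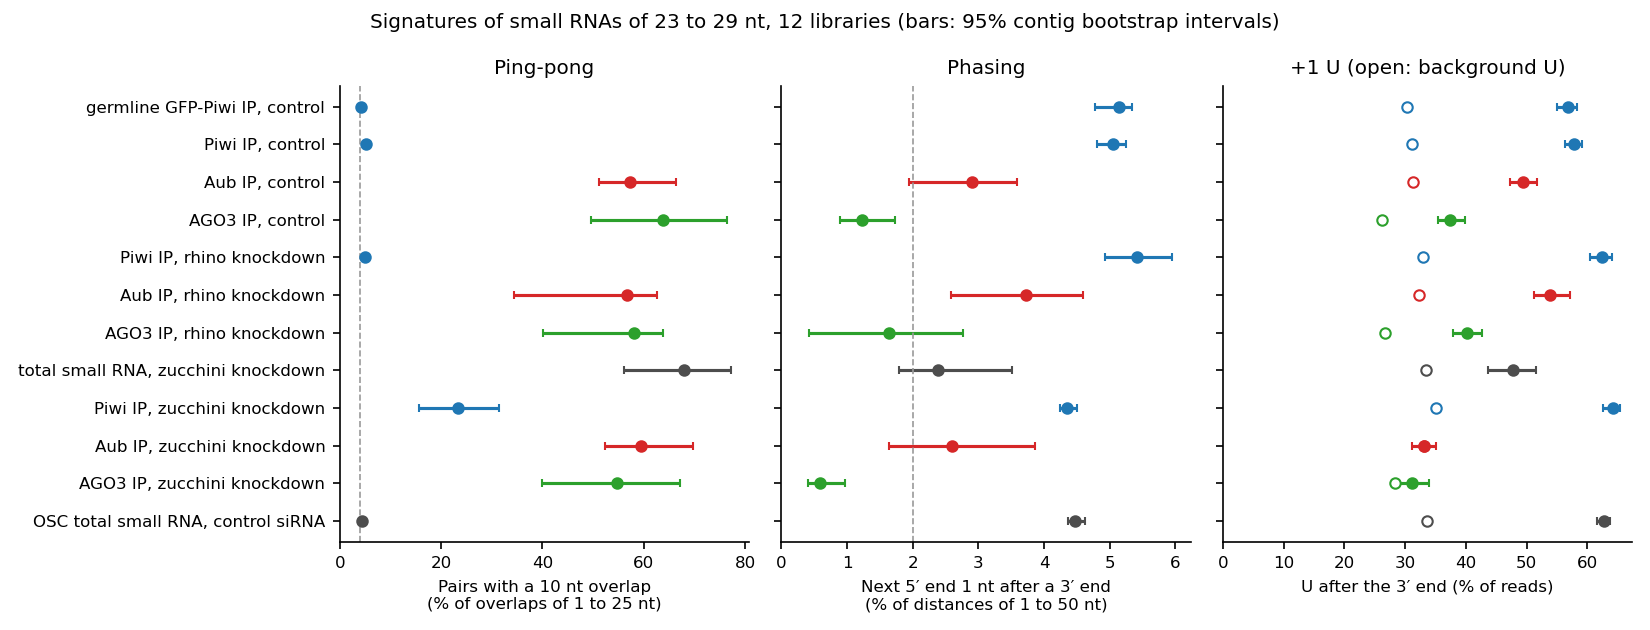
Ping-pong, phasing and +1 U shares (x axes, in %) of the 12 libraries (rows), with 95% contig bootstrap intervals as bars, the even share as a dashed line and the background U share as open circles. Aub and AGO3 libraries lie between 54.8% and 63.8% in ping-pong share, and the zucchini knockdown Piwi IP is at 23.4% against 5.25% in its control.

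The GFP-Piwi IP, whose column was matched to its sample by name alone, was set against the Piwi IP of control ovaries to part germline from follicle cell piRNAs. Elements of the follicle cells were depleted from it. flamenco was 23.8-fold lower (log2 −4.57, −4.74 to −4.41), ZAM 13.9-fold, gtwin 12.4-fold, mdg1 8.18-fold and gypsy 3.82-fold. All 3 measured soma-dominant transposons were at least 2-fold lower, with a median log2 of −3.63, at percentile 1.69 of random lists. Germline elements stayed closer to the Piwi IP. Of the 6 germline-dominant transposons 0 passed 2-fold (median log2 −0.33, percentile 30.6), the dual-strand cluster 42AB was 1.72-fold higher and cluster 20A 2.69-fold higher. Scaling to microRNA reads raised every log2 ratio of this comparison by 0.91. That took at least the highest of the 6, at 0.55, past 2-fold and turned their median positive. The 11 other transposons had a median log2 of −0.70 (percentile 4.31), and 4 of them were at least 2-fold lower.

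OSC piRNAs, which come from a somatic line, differed from the ovary Piwi IP in the same elements. gypsy was 8.19-fold higher (log2 3.03, 3.02 to 3.05), ZAM 5.49-fold, gtwin 5.41-fold and flamenco 4.76-fold, but of these gypsy alone stayed higher when the libraries were scaled to microRNA reads. Max-element (log2 −11.27), cluster 42AB (−8.67), HeT-A (−8.43) and Burdock (−8.26) were lower under all 4 scalings. The soma-dominant list had a median log2 of 2.46 and the germline-dominant list of −7.55, at percentiles 93.1 and 0.52. The OSC library was total RNA set against an IP. Of 1605 contigs, 726 were higher and 696 lower, and higher contigs made up 51.1% of these calls against 16.2% under microRNA scaling; for GFP-Piwi 69 of 1292 were higher and 320 lower, 17.7% against 71.3%.

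The rhino knockdown asked which piRNAs need Rhino, a heterochromatin protein 1 homolog that binds dual-strand clusters and is needed for their transcription. In it, cluster 42AB piRNAs were 83.8-fold lower in the Piwi IP (log2 −6.39, −6.62 to −6.17), 53.9-fold lower in Aub (−5.75) and 24.3-fold lower in AGO3 (−4.60). invader1 (−5.26, −5.58 and −4.47), TART (−4.10, −3.99 and −2.50), DM1731 (−3.52, −4.19 and −2.73) and Burdock (−2.85, −3.60 and −3.16) were lower in each IP, as were Max-element, accord and 42AB, under all 4 scalings. The uni-strand cluster 20A was higher in Piwi, Aub and AGO3 (log2 2.09, 2.49 and 1.43), and so was the I-element (2.17, 0.47 and 1.75). The LTR retrotransposon DM297 was 6.71-fold higher in Piwi and 7.23-fold in Aub, again under all 4 scalings. flamenco was higher in Piwi (0.98) and Aub (1.03), and its 0.75 in AGO3 turned negative under microRNA scaling.

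By list, 4 of the 6 germline-dominant transposons were at least 2-fold lower in the rhino knockdown Piwi IP and 1, the I-element, was higher, with a median log2 of −2.28 (percentile 7.69). Their median was −3.00 in Aub (percentile 43.4) and −2.21 in AGO3 (percentile 22.2). The 3 soma-dominant transposons had medians of 0.61 in Piwi (percentile 62.5), −1.96 in Aub (percentile 59.5) and −0.82 in AGO3 (percentile 50.2), and the last pair turned to 0.63 and 0.46 with the median contig set to 0. Of these, gypsy was lower in Aub (−4.02) and AGO3 (−2.35) under all 4 scalings, while the direction of ZAM and gtwin turned with the scaling there. In the other transposons the medians were −0.53 (percentile 23.4), −1.51 (77.5) and −0.50 (60.4), and for the uni-strand clusters flamenco and 20A they were 1.53 (93.9), 1.76 (86.8) and 1.09 (61.3). Of all 23 elements, 9 were higher and 10 lower in Piwi under all 4 scalings, 4 and 8 in Aub, and 4 and 10 in AGO3. blood was lower in Aub (−1.46, not under every scaling) and higher in AGO3 (1.28), and jockey was higher in AGO3 alone (1.78).

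Across the contigs with at least 1000 reads, the Aub-enriched class had a lower median in the rhino knockdown IPs under all 4 scalings, and the OSC-enriched class a higher one in Piwi. Median log2 ratios of the Aub-enriched class were −3.66 in Piwi, −3.93 in Aub and −2.78 in AGO3, against 0.94, 0.12 and 0.64 for the OSC-enriched class, which turned to −0.19 in Aub and −0.62 in AGO3 under microRNA scaling; the control Aub IP serves both in the class and in the Aub ratio. In Piwi 457 of 1574 contigs were higher and 597 lower, in Aub 283 and 683 of 1081, and in AGO3 310 and 533 of 1025. The 8 lowest Piwi contigs (log2 −8.30 to −7.17) were all Aub-enriched and the 8 highest (6.40 to 7.79) were all of the intermediate class, and none carried a named element. A contig with few reads in both OSC and the control Aub IP falls in the intermediate class by definition. The medians of all contigs were 0.38, −2.59 and −1.29, so ratios depend on the scaling. Higher contigs made up 43.4%, 29.3% and 36.8% of the calls, against 32.2%, 51.6% and 52.6% with the median contig set to 0, and against 60.2% in Piwi and 26.3% in AGO3 under microRNA scaling.

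Zucchini is the endonuclease of the mitochondrial surface in piRNA biogenesis, and in its germline knockdown few cluster 42AB piRNAs were left in any IP. 42AB was represented by 4 Piwi reads (log2 −10.55, −12.42 to −9.19), 8 Aub reads (−8.64) and 5 AGO3 reads (−8.04). Burdock (−9.06, −9.05 and −8.62), HeT-A (−5.78, −8.70 and −8.71) and the I-element (−4.77, −8.75 and −10.51) were lower in each. Such low levels carry wide counting error. In Poisson draws of the counts, the germline-dominant list median spanned −6.70 to −5.91 in Aub and −7.20 to −6.42 in AGO3. In the Piwi IP flamenco was 4.41-fold higher (log2 2.14, 2.11 to 2.17), gypsy 2.40-fold, gtwin 1.81-fold and ZAM 1.71-fold, and of the other transposons DM412, mdg1 and blood were higher by 3.58-fold, 3.08-fold and 2.63-fold, with a list median of −1.80 (percentile 9.68). These 7 elements were higher and 13 lower under all 4 scalings. The OSC-enriched contigs had a median log2 of 1.81 in this IP, with 334 of 387 at least 2-fold higher. gypsy, gtwin, ZAM, mdg1 and blood lay below that median. An IP ratio is relative to the rest of its library, so a gain cannot be told from a loss of other piRNAs.

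In Aub and AGO3 the zucchini knockdown split the germline elements. Max-element was 1.63-fold lower in Aub and 1.81-fold in AGO3, and TART 1.45-fold and 1.86-fold, and their direction turned with the scaling, whereas in Piwi they were 26.3-fold and 14.2-fold lower under all 4. copia was 2.87-fold higher in Aub and 2.04-fold higher in AGO3, the latter under all 4 scalings, and 3.47-fold lower in Piwi (not under every scaling). roo was 1.30-fold higher in Aub and 2.71-fold lower in AGO3, neither under every scaling. Of the 23 elements 15 were lower and 0 higher in Aub under all 4 scalings, and 13 and 1 in AGO3. The 6 germline-dominant transposons had a median log2 of −4.94 in Piwi (percentile 3.40), −6.45 in Aub (percentile 3.0) and −6.85 in AGO3 (percentile 3.10); in Piwi all 6 were at least 2-fold lower, and 4 of 6 in Aub and in AGO3. The soma-dominant list had medians of 0.86 in Piwi (percentile 51.6), −2.62 in Aub (percentile 61.1) and −2.27 in AGO3 (percentile 60.97), and the last pair turned to 0.25 and 0.95 with the median contig set to 0.

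**Figure D2:**
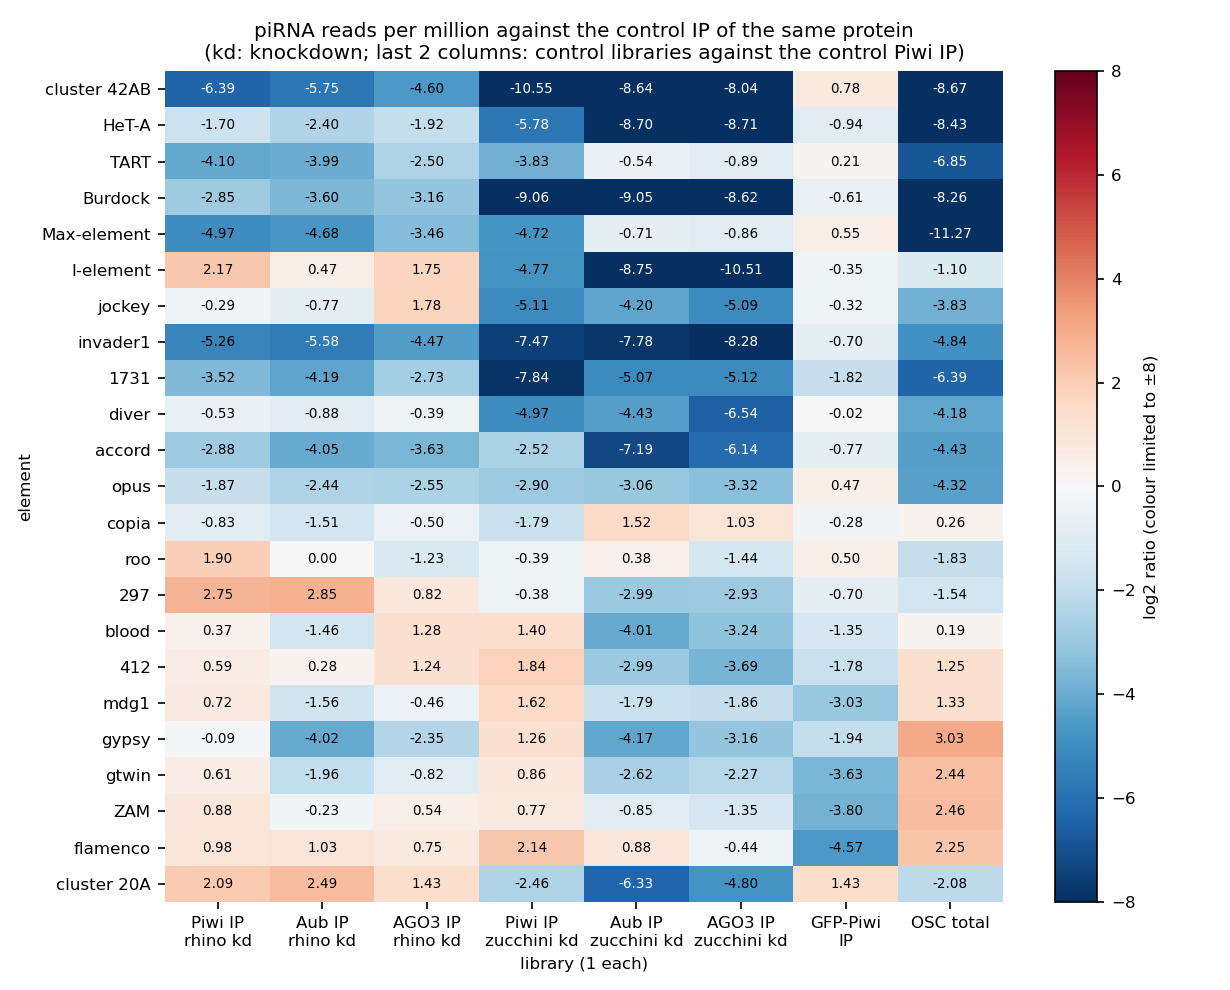
log2 ratios of scaled reads for the 23 named elements (rows) in the 6 knockdown IPs against the control IP of the same protein and in GFP-Piwi and OSC against the control Piwi IP (columns), 1 library each, with the value in each cell. Cluster 42AB is lower in all 6 knockdown IPs under all 4 scalings, from −4.60 to −10.55, and flamenco is higher in both knockdown Piwi IPs.

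The share of 23 to 29 nt Piwi reads on OSC-enriched contigs was 12.2% in control, 21.7% in rhino knockdown and 41.7% in zucchini knockdown, and that on Aub-enriched contigs was 33.4%, 14.3% and 6.82%. In the zucchini knockdown Piwi IP, 409 of 1236 contigs were higher and 673 lower, in Aub 116 and 582 of 879, and in AGO3 81 and 551 of 770. Higher contigs made up 37.8%, 16.6% and 12.8% of the calls, against 51.0%, 49.0% and 47.2% with the median contig (−1.88, −2.87 and −3.23) set to 0, and 3.55% in Aub under microRNA scaling. The 8 lowest contigs of the Piwi IP had log2 ratios of −11.57 to −10.64. 2S rRNA took 40.4% of all Piwi reads, 41.3% of Aub reads and 77.4% of AGO3 reads in these libraries, against 0.455%, 1.56% and 0.5999% in control. Most of it was 30 nt long and so outside the reads compared, but the rest lay among them. Scaling without 2S rRNA, tRNA and microRNA raised every log2 ratio by 0.10 in Piwi, 0.096 in Aub and 0.39 in AGO3.

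U after the 3′ end separated the 2 knockdowns in Aub and AGO3 but not in Piwi, where its share was higher in both. In the zucchini knockdown it followed 33.1% of Aub reads, the same as the background of 33.1%, and 31.1% of AGO3 reads with a background of 28.3%; the change from control was −16.4 percentage points in Aub (−18.2 to −14.1) and −6.36 in AGO3 (−8.65 to −3.73). In Piwi it was 64.2%, 6.45 points above control (5.30 to 7.52), while its background was 35.0% against 31.1%. Within classes the Piwi share moved less, from 65.7% to 66.1% on OSC-enriched, from 60.1% to 63.5% on intermediate and from 52.9% to 55.1% on Aub-enriched contigs, where the background went from 28.4% to 34.0%. In the rhino knockdown the +1 U share was higher by 4.65 points in Piwi (3.11 to 6.01), 4.43 in Aub (2.12 to 7.64) and 2.68 in AGO3 (0.323 to 5.38), with backgrounds of 32.9%, 32.3% and 26.6% against 31.1%, 31.3% and 26.1% in control.

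Ping-pong between Aub and AGO3 was 69.3% (48.2 to 72.9) in the rhino and 69.9% (62.8 to 77.3) in the zucchini knockdown. The ping-pong share of the Piwi IP was 23.4% in the zucchini knockdown, 18.2 points above control (10.4 to 26.1). On Aub-enriched contigs it was 43.2% there against 5.47% in control, and on OSC-enriched contigs 4.86% against 5.35%. In Aub and AGO3 the interval of the change included 0 in each knockdown, but it was too wide to show an unchanged share. In the rhino knockdown it ran from −24.4 to 7.95 in Aub and from −28.5 to 10.1 in AGO3. In the zucchini knockdown it ran from −1.37 to 10.3 and from −23.85 to 5.88. In the rhino knockdown 1 contig gave 76.2% of the 10 nt pairs of Aub, whose share was 56.6% with it and 40.2% without it, and in AGO3 1 contig gave 68.5%, with 57.97% and 45.2%. In the zucchini knockdown the phasing share changed by −0.704 points in Piwi (−0.903 to −0.451) and by −0.634 in AGO3 (−1.08 to −0.230), and the Piwi change was 0.0512 with each position counted once.

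The reporters carried a target site for an abundant trigger piRNA, and the sense small RNAs 3′ of the site were measured. With the trigger site, antisense reads began at position 771 and responder reads, sense reads overlapping the trigger by 10 nt, at position 762. The sense signal downstream of the site was 1049 (1004 to 1095), against 55.5 (46.1 to 66.2) in the reporter with a control target, a log2 ratio of 4.24 (3.98 to 4.52). Over the nearest 150 nt it was 552 against 4.55. Upstream the signals were 8.59 and 9.55, a difference within counting error. The control target gave 0 reads at either position, and the responder signal with the trigger was 118, at least 86.3-fold above the floor of 3 counts.

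Mismatches in the trigger site were placed at positions 4 and 5 or at 16 and 17 of the piRNA, by the labels. With the 5′ mismatch the responder signal was 2.90 (1.06 to 6.31) and the downstream signal 123 (109 to 139), 11.7% of that with the matched trigger (10.3 to 13.4) and 2.22-fold that of the control target. With the 3′ mismatch the responder signal was 179 (160.2 to 200.1) and the downstream signal 1278 (1226 to 1332), 1.22-fold the matched value, but 0.92-fold over the nearest 150 nt (508 against 552, a difference within counting error). Per 100 trigger reads the responder reads numbered 9.61, against 9.16 with the matched trigger. The trigger itself was present in both, with antisense signals of 1389 and 1866 at its 5′ end against 1285.

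The reporters with U runs asked whether U downstream of the site goes with where the following small RNAs begin. The runs were spaced by 26 nt in 1 reporter and by 27 falling to 23 nt in another, and total downstream signals were 1179 (1137 to 1222) and 850.0 (803 to 899). In the evenly spaced reporter the top positions were 787, 813 and 812, with signals of 185.3, 87.3 and 43.3, and in the decreasing one 790, 817 and 843, with 157, 81.3 and 42.4. The reporter without runs had 1 dominant position, 787, with 162. Within 1 nt of a grid of 6 positions at 26 nt lay 63.5% of the reads of the even reporter (61.1 to 65.8), 33.8% of the reporter without runs and 10.4% of the decreasing reporter, with 11.5% for an even spread. On the decreasing grid these were 65.7% of the decreasing reporter (62.1 to 69.2), 21.2% without runs and 5.82% of the even reporter. Each grid started at the highest position after the site in its own reporter, so that peak lay on it by construction. The share of a reporter on its own grid is therefore partly fixed in advance against an even spread. Position 787 alone held 321 of the 383 reads that the reporter without runs had on the even grid. The strongest autocorrelation fell at lags of 26 nt in the even, 27 nt in the decreasing and 29 nt in the plain reporter. The responder signals with U runs were 416 and 486, 3.53-fold and 4.13-fold that without runs.

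**Figure D3:**
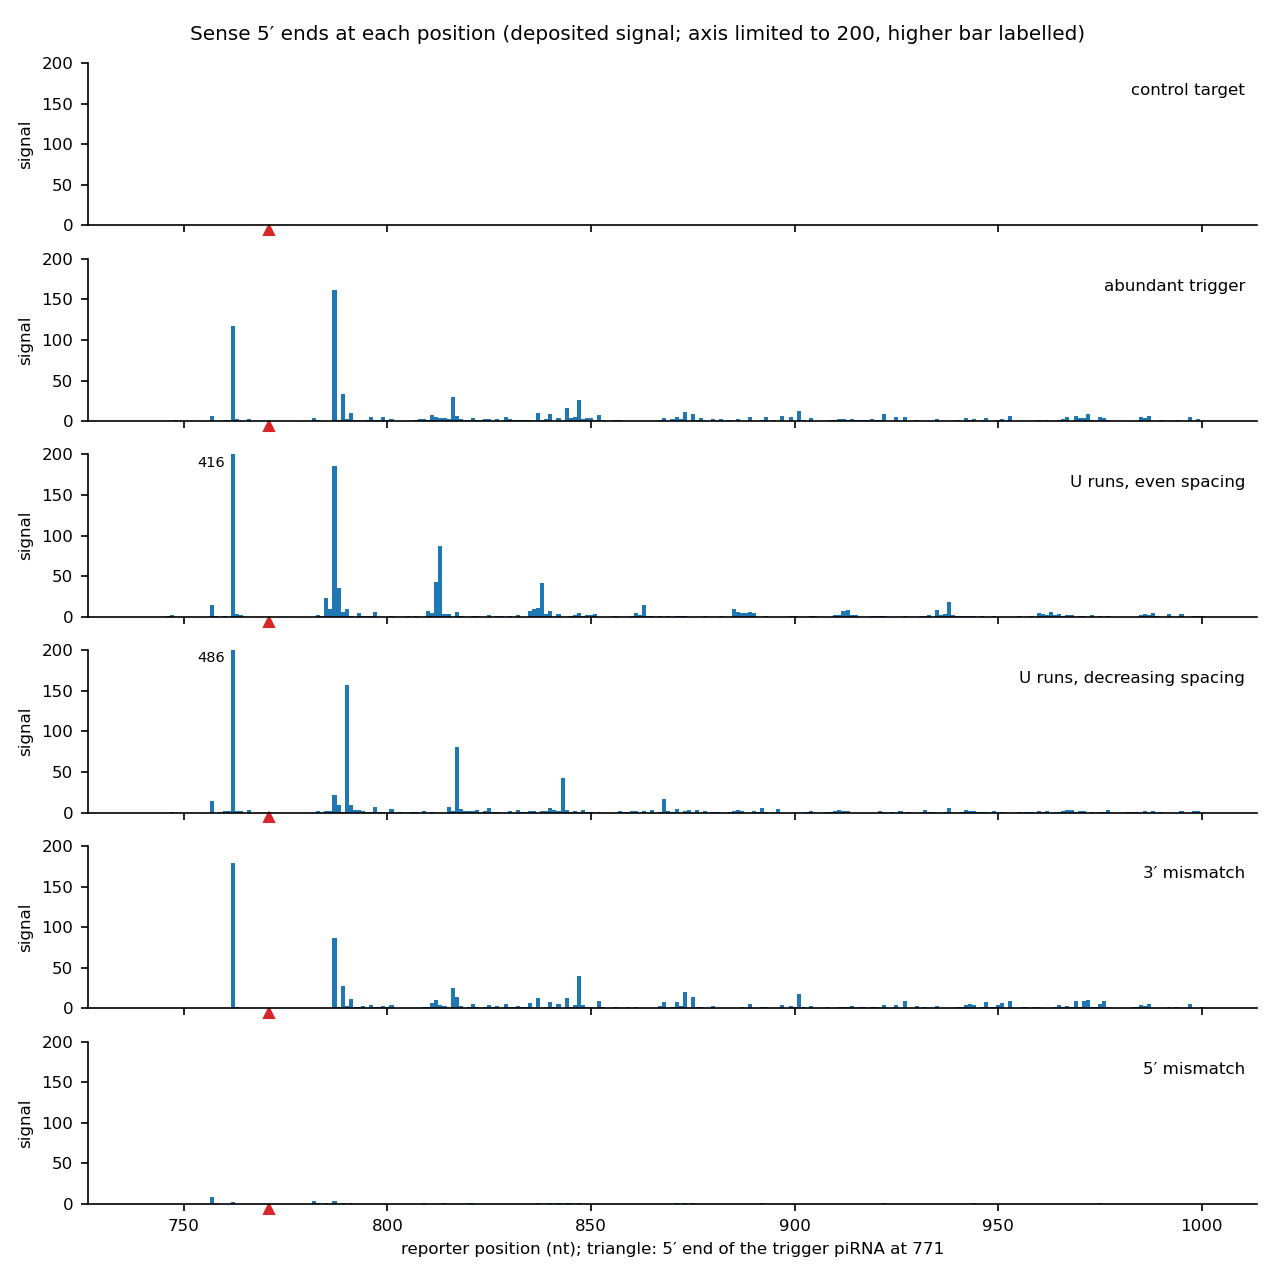
Deposited signal of sense 5′ ends (y axis, limited to 200) by reporter position in nt (x axis) in the 6 trigger reporters, with the trigger 5′ end at 771 as a triangle. Peaks follow the responder at 762 at 787, 813 and 838 with even U runs and at 790, 817 and 843 with decreasing ones, and the 5′ mismatch and control target show almost none.

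The last 4 reporters had 1 site, 2 sites, 3 sites or 2 sites 100 nt apart for piRNAs that persist without Zucchini, in control and zucchini knockdown. Few small RNAs were left 3′ of the last site in the knockdown. Downstream sense signals were 0.203% of control (0.0744 to 0.442) with 1 site, 1.10% (0.641 to 1.77) with 2 sites, 4.49% (2.69 to 7.05) with 3 sites and 1.13% (0.565 to 2.03) with distant sites. Responders were retained where a further site lay 3′ of them. The responder of the site at position 775 kept 3.38% (1.92 to 5.54) as the only site, 32.0% (24.8 to 40.9) with 1 further site, 91.5% (71.9 to 115.6) with 2 further sites and 28.5% (22.2 to 36.1) with a distant site. Per antisense trigger read these shares were 3.20%, 23.0%, 50.6% and 42.1%, so their size and order depended on the scaling. That of the site at 828 kept 2.82% (1.21 to 5.61) as the last and 59.3% (44.3 to 78.4) with a further site, and 2.09% and 25.2% per trigger read.

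At the site at 874, last in both reporters that carried it, the responder had 2 reads in the knockdown of the reporter with 3 sites (2.87% of control, 0.345 to 10.5) and 0 of the distant reporter (276 reads in control, upper limit 1.95%). Between the trigger 5′ ends of the distant sites, 1026 sense reads in control became 0 in the knockdown, which allows up to 0.522%. The 276 reads of the last responder are among these 1026. Total sense signals were 0.717%, 5.22%, 24.6% and 5.21% of control, log2 ratios of −7.12, −4.26, −2.02 and −4.26. The triggers persisted, with antisense signals between 67.1% and 306% of control; scaled to them, the log2 ratio of the reporter with 3 sites was −3.24, and with both strands together it was 0.61. Intervals are wide where few reads remained, since the knockdown libraries held 25, 116, 205 and 104 sense reads.

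**Figure D4:**
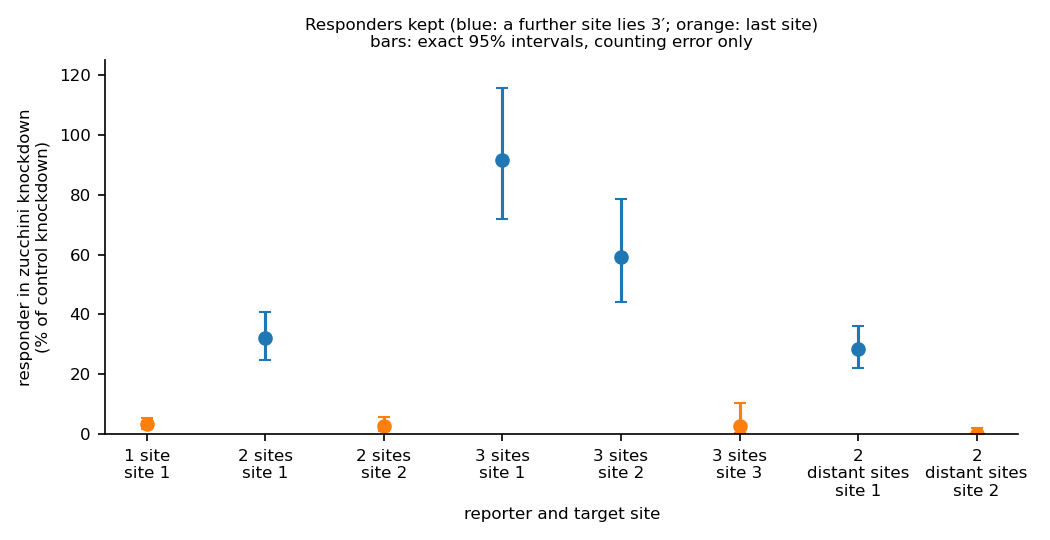
Responder signal in zucchini knockdown as a percentage of control (y axis) for each site of the 4 reporters (x axis), with exact 95% intervals that cover counting error only. Responders with a further site 3′ (blue) kept 28.5% to 91.5% and those of the last site (orange) 0% to 3.38%, or 23.0% to 50.6% and at most 3.20% per antisense trigger read.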

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

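All tests in this part were chosen after the results were seen. Some elements moved at least 2-fold in opposite directions in 2 IPs of the same knockdown; each difference below is between log2 ratios of single libraries and was not tested. In the zucchini knockdown, DM412, blood, gypsy and mdg1, all LTR retrotransposons, were at least 2-fold higher in Piwi and at least 2-fold lower in both other IPs. With the median contig set to 0 the sign in the other IPs turned for mdg1 in Aub (1.08) and AGO3 (1.37) and for gypsy in AGO3 (0.06). The differences between the Piwi and Aub ratios were 4.83 for DM412, 5.41 for blood, 5.44 for gypsy and 3.42 for mdg1, and between Piwi and AGO3 they were 5.53, 4.64, 4.43 and 3.48. copia went the other way, at −3.32 against Aub and −2.83 against AGO3, and its sign in Piwi and Aub depended on the scaling. In the rhino knockdown the Piwi ratio of roo was 3.13 above that of AGO3, and the Aub ratio of blood differed from that of AGO3 by −2.74; the signs of roo in AGO3 and of blood in Aub depended on the scaling.

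A further signal lay in reads of 30 nt, which the comparisons leave out. 2S rRNA of that length made up 35.8% of the reads of the Piwi IP, 36.7% of the Aub IP and 70.7% of the AGO3 IP in the zucchini knockdown, above the 0.396%, 1.43% and 0.537% of control. Less piRNA in the IP, so that every background RNA takes a larger share, was argued against as the whole cause: relative to the other reads 2S rRNA was at least 44.3-fold higher, while tRNA or microRNA reads were at most 3.43-fold higher. Removal of 2S rRNA from some libraries and not from others stays open, because the labels give no preparation per library. In the total RNA library of the same knockdown, 2S rRNA of 30 nt made up 0.00058% of the reads, and 2S rRNA of all lengths 1.70%. Reads of 30 nt of any kind made up 0.033% of that library, against 36.7%, 38.5% and 71.3% of the Piwi, Aub and AGO3 IPs. No biological explanation was tested.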

How the results depend on the processing

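The tests chosen after the data were seen were the minimum of 3 sequences per word, the leaving out of top contigs, both scalings and first-base shares without rRNA, tRNA and microRNA, contig counts with the median contig set to 0, and the scaling per antisense read. Of 201 values of main answers recomputed under alternatives, 132 moved less than their interval or stayed within 1.5 times the count, 62 moved further with the same sign and 7 reversed. Of 60 other values, 26 stayed and 34 moved. A reversal was counted only where the main interval left out 0, so the 132 include changes of sign. With each position counted once, 5 of 9 ping-pong differences kept their sign. Without the top contig, 7 of 9 phasing differences did. Ping-pong and phasing shares moved within their intervals with all lengths, with a minimum of 3 sequences per word, or without the top contig. Where no cause is given below, the cause was not tested.

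With each position counted once, ping-pong differences were 0.148 points for Aub and 0.661 for AGO3 against Piwi, −0.0118 for GFP-Piwi, and 0.811 for Piwi in the zucchini knockdown. Phasing differences were −0.0808 for Aub and −0.155 for AGO3 against Piwi and −0.139 for AGO3 in the zucchini knockdown, and that of Piwi reversed to 0.0512. The +1 U differences were −3.50 for Aub and −7.92 for AGO3 against Piwi, 1.95 for Piwi in the rhino knockdown, and 5.21 for Piwi and −7.35 for Aub in the zucchini knockdown; that of GFP-Piwi reversed from −0.993 to 0.485.

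With at least 500 reads more contigs count. In the rhino knockdown 884 were then higher and 924 lower in Piwi and 448 higher in Aub; in the zucchini knockdown 615 were higher and 1047 lower in Piwi, and 113 were higher in GFP-Piwi. Scaled to microRNA reads, 802 were higher in the rhino Piwi IP, 27 in the zucchini Aub IP, 42 in the zucchini AGO3 IP and 600 in GFP-Piwi. With the median contig set to 0, 302 were higher in the rhino Piwi IP. In rhino Aub 446 were higher and 419 lower, in zucchini Aub 357 and 371, and in zucchini AGO3 298 and 333.

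Setting the median contig to 0 shifts every ratio of a comparison by the same amount. The soma-dominant medians in Piwi, Aub and AGO3 became 0.23, 0.63 and 0.46 in the rhino knockdown and 2.74, 0.25 and 0.95 in the zucchini knockdown, reversed in Aub and AGO3 of each. The germline-dominant medians became −2.66, −0.41 and −0.92 in the rhino and −3.06, −3.58 and −3.62 in the zucchini knockdown. Without rRNA, tRNA and microRNA reads, the soma-dominant medians were −1.50 in rhino Aub, 0.96 in zucchini Piwi and −1.88 in zucchini AGO3, and the germline-dominant ones −2.54 in rhino Aub and −4.84 in zucchini Piwi.

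Over the nearest 150 nt downstream of the reporter target, log2 ratios against the control target were 6.92 with the trigger, 7.21 with even and 6.77 with decreasing U runs, 3.05 with the 5′ mismatch and 6.81 with the 3′ mismatch. With positions capped, the strongest lags were 28 nt without U runs, 25 nt with even and 28 nt with decreasing ones. At the exact grid position lay 41.2% of the even and 60.7% of the decreasing reporter. Without the highest position, the log2 ratios of sense reads in the zucchini knockdown were −8.39 with 1 site, −5.83 with 2, −2.81 with 3 and −6.34 with distant sites. With both strands together they were −2.48, −0.55, 0.61 and −1.75, and that with 3 sites reversed. This reversal came from the antisense reads, whose signal with 3 sites was 2846 in the knockdown against 1305 in control. Of the 2846, 495, 1434 and 528 lay at the trigger 5′ ends. The sense signal was 164 against 666. Per antisense read at the triggers, the log2 ratios of sense reads were −4.71 with 2 sites, −3.24 with 3 and −3.69 with distant sites.

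Alternatives that need unique mapping to a genome, reads of 20 to 22 nt or the length of reporter reads were not run, as these files do not give them. No paired analysis was possible because each group was 1 library. Low counts limit the zucchini knockdown values, where cluster 42AB rests on 4 to 8 reads and the reporters on 25 to 205 sense reads.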

Other observations

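All tests in this part were chosen after the results were seen. The total small RNA of the zucchini knockdown had a ping-pong share of 67.9% (56.1 to 77.1), a phasing share of 2.38% and a +1 U share of 47.7%, with a background of 33.5%. microRNA reads of 23 nt or more made up 7.79% of it, against 1.77% in OSC. tRNA fragments made up 28.1% of the reads of the rhino knockdown Aub IP. AGO3 held a larger sense share than Aub in 17 of 23 elements in the rhino and 14 of 23 in the zucchini knockdown.

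In the zucchini knockdown, responders with a further site 3′ were kept and those of the last site were not. A smaller scaling factor of the knockdown libraries was argued against, since within a library pair the retained share of the site at 775 was higher than that of the last site by a factor of at least 5.38 (the lowest 95% bound over 3 reporters). Zucchini left after the knockdown was argued against as the whole cause, since at most 4.49% of the sense signal downstream of the last site remained. A candidate explanation is that a cut at a site further 3′ supplies the end of the responder: the lowest share with a further site was 28.5% and the highest without one 3.38%, or 23.0% and 3.20% per antisense trigger read. This remains a hypothesis, because it was found and tested on the same 8 sites.

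In the rhino knockdown, 40 contigs were at least 16-fold higher in Piwi, with 26160 rpm against 897.5 in control, and 37 of them were of the intermediate class. That class also takes contigs with few reads in both OSC and the control Aub IP, so it is no trait of their source. A variant, at least 85% identical, of a sequence that gives piRNAs in the control was looked for among the contigs. Of the 40 contigs 0 had such a partner (upper limit 8.81%), against 24.04% of unchanged contigs. This argued against a variant with a contig of its own. A counterpart shorter than 100 nt, or joined into the same contig, would be missed, so the explanation is not excluded. The upper limit also takes the 40 contigs as independent, which pieces of the same element would not be. Reads carried over from another library of the shared table were argued against, with 0 contigs higher in any of its 8 libraries of another genotype, the control Piwi IP used for the selection left out; the reporter libraries could not be compared. A source of piRNAs that opens when rhino is reduced stays open, and so does a difference between fly strains, since the labels give no strain. Of the 40 contigs, 39 were at least 4-fold higher in Aub and AGO3 too. Either explanation would give that rise, so it cannot tell them apart.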
